A study of Homo sapiens with 3 samples.

How the data were processed

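Total RNA of SAS cells was hybridised on 3 Affymetrix Human Gene 2.0 ST arrays, of which 2 carry the label ARID1A siRNA and 1 the label mock, per the labels. Per the submitters' processing notes, the authors used Affymetrix Expression Console. Its version, the summary of probes, the background correction and the genome build are not given in the sources used here, so positions are given as chromosomes only. The deposited value table holds log2 expression per probe set, normalized by the authors. The authors' deposited per-sample tables hold the same values as linear intensity, equal on the log2 scale to within 5e-05. They also hold the ratio of each siRNA array to the mock array, with a flag for 2-fold differences above the negative control mean, per the file headers. In the authors' deposited table the flag marks 27 probe sets as higher on array 108 and 59 on array 109, with 8 on both, and 82 and 114 lower, with 16 on both.

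Of 53617 probe sets, 31134 had 1 gene symbol, 1 a double symbol and 22482 none. Symbols were updated through the Entrez identifier for 29766 probe sets. All 4740 probe sets that the deposited table marks as cross-hybridising had no single symbol. Probe sets of a gene were averaged, which affected 1435 of 29402 genes, and genes with a mean log2 value under the 30th percentile, 3.52, were left out, leaving 20582. A gene below the negative control mean on the mock array was compared as at least N-fold against that mean, and so was a gene below it on one siRNA array in the comparison of the siRNA arrays. Ranks use the measured values.

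The comparison was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend, two-sided, Benjamini-Hochberg adjustment), with 1 residual degree of freedom. The mock array is assumed to vary like the siRNA arrays. This design, 40 gene lists, the rule for named genes and the alternative settings were fixed before the data were examined. Genes with tied siRNA values, 9918 in all, have a spread of 0, which brought the prior degrees of freedom down to 0.279 and the median prior SD to 0.000157. A fit on the 10664 untied genes (prior degrees of freedom 4.9, prior SD 0.157) and a fit applying that prior to all genes were added after seeing the data. Because the tied genes were left out of it, that prior may overstate the spread of the tied genes.

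Lists were tested with limma camera at a preset correlation of 0.01, whose statistics use the same prior and so are touched by the ties. That setting treats the members of a list as nearly independent, so its p-values may be too small where members move together. With 1 residual degree of freedom, an estimated correlation measures only how far the list moved between the siRNA arrays. The limma camera test with an estimated correlation rests on that 1 degree of freedom too. It gave adjusted p = 0.999 for each of the 40 lists, so it cannot tell them apart. Each list mean was set beside 10000 random lists matched over 20 bins of level. The design had named the list median for this, and the text uses the mean. Where a list set against random lists in the text has another outcome by the median, that is stated. Adjusted over the list alone, with the prior of the untied genes, 3 NF-kB genes passed as higher, and 1 gene each of the immediate early, TGF-beta, YAP/TEAD, ATF4 and ARID1A-linked lists, some of them shared between lists. As lower, 2 TGF-beta targets, 1 histone gene and 1 matrix protease gene passed. In the other lists 0 passed, and over all genes tested 0 passed in any list.

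The methods were tested on simulated data for 20582 genes, made by resampling the real residuals with their ties, with 50 genes at each of several log2 changes. Of genes with a log2 change of 1, the designed fit called 62%, the prior of the untied genes 8% and the 2-fold rule in both arrays 72%. At a log2 change of 2 these were 58%, 94% and 100%. They called 1874, 13 and 33 unchanged genes. A shift of 0.3 in the simulated NF-kB list was called by limma camera, with 0 of the other lists called. The shift was equal on both siRNA arrays and the ties were kept, so tied members had a spread of 0. This call therefore does not measure the power of the test for the real lists.

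The text names ARID1A, then the 12 higher and 12 lower genes with the largest change, taken as the smaller of the differences on the siRNA arrays. Genes past the false discovery rate and 2-fold on both arrays came first, and the places left were filled by the same ranking without the test. Up to 4 genes per described list and 6 genes each way between the siRNA arrays are named too. Uncharacterised loci, microRNAs and small nucleolar RNAs were counted but not named among the 24. CSF1R and MIR501 fall outside the rule and were chosen after their values were seen.

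Alternatives covered the filter, quantile, median and cyclic loess scaling, the highest probe set per gene, the limma prior, a test against 1.2-fold, the thresholds, the list test, the source of the values and leaving out each siRNA array. Gene ontology terms of the deposited annotation were tested by a one-sided hypergeometric test, added after seeing the data. Figures were drawn with matplotlib 3.10.9.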

Results

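Gene expression was measured in SAS cells, a human squamous carcinoma line from the tongue, with Affymetrix Human Gene 2.0 ST arrays. The series held 3 arrays. Of these, 2 came from cells transfected with siRNA against ARID1A and 1 from mock cells. The siRNA arrays are replicate 1 and replicate 2, called array 108 and array 109 here after the numbers in their titles, whose meaning the labels do not give. The title of the mock array is SAS NC, and the labels do not explain NC or say whether the mock cells received a control siRNA. Nor do they say whether the siRNA arrays came from separate cultures, so the spread between the siRNA arrays may be technical. The number of arrays limits the precision of every value, and the mock array has no replicate. Median log2 values were 3.97, 3.99 and 3.97 for array 108, array 109 and the mock array. The authors' negative control mean lay at log2 4.36, 4.65 and 4.43, and 51.3%, 45.4% and 49.7% of 29402 genes lay above it. Of the 20582 genes tested, 38% had exactly the same value on all 3 arrays and 48.2% on both siRNA arrays.

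The comparison in the series title asks how ARID1A knockdown alters gene expression in SAS cells. ARID1A on chromosome 1, a subunit of the SWI/SNF chromatin remodelling complex, was at log2 5.72 on array 108 and 5.32 on array 109, against 6.79 on the mock array. This was 2.10-fold and 2.77-fold lower, with a mean log2 difference of -1.27 ± 0.28 (SD, n = 2). The direction matched the labels on both arrays, but ARID1A did not pass the designed limma test (adjusted p = 0.755), in which the ties distort the spread. On untied genes alone it did not pass either (limma adjusted p = 0.664). Both adjustments cover every gene in the fit, not the target alone. Of 26 other SWI/SNF subunits tested, 2 were higher and 5 lower than in the mock array on both siRNA arrays. Among them, SMARCA4, an ATPase of the complex, differed by 0.12 and 0.53, SMARCB1 by -0.17 and -0.18, and ARID1B, the paralog of ARID1A, by -0.05 on each. The mean of these subunits was -0.07 on array 108 and 0.04 on array 109, with limma camera adjusted p = 0.569, and its sign depended on the scaling of the arrays.

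NF-kB target and cytokine genes were higher than in the mock array on both siRNA arrays. Of 28 members tested, 16 were higher on both arrays and 2 lower, and 9 were at least 1.5-fold higher on both. CXCL1, a neutrophil chemokine on chromosome 4, differed by 1.55 and 1.87. Its mock value lay below the negative control mean, so it was at least 2.79-fold higher. TNFAIP3, a feedback inhibitor of NF-kB, differed by 0.83 and 1.70, and NFKBIZ, an atypical nuclear IkB protein, by 0.83 and 1.31. The list mean was 0.33 on array 108 and 0.60 on array 109, above the central 95% of 10000 random lists matched on level for each array. The list did not pass limma camera as designed (adjusted p = 0.336). It passed in 6 of 10 alternatives. The lowest limma camera adjusted p was 1.79e-18, on untied genes, chosen after seeing the data and with list members treated as nearly independent. The highest was 0.999 with an estimated correlation, where every list had that value.

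Immediate early and AP-1 genes, which respond within minutes to growth factors and stress, were also higher on both arrays in 12 of 25 members and lower on both in 0. ATF3, a stress-induced transcription factor, differed by 0.96 and 1.02, DUSP1, a MAP kinase phosphatase, by 0.71 and 0.61, and KLF6 by 0.53 on each array. The list mean was 0.20 on array 108 and 0.35 on array 109. Its adjusted p from limma camera was 0.0988, and it passed in 6 of 10 alternatives. With an estimated correlation it had limma camera adjusted p = 0.999, as did every list. Among 10 leukocyte markers, CSF1R, a macrophage growth factor receptor, differed by 0.97 and 0.72, and the other 9 had a mean of 0.009 on array 108 and -0.005 on array 109.

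Cell-cycle genes were lower on both siRNA arrays. Of 39 mitosis and G2/M genes, 35 were lower than in the mock array on both siRNA arrays and 0 were higher on both. KIF20A, a mitotic kinesin, differed by -0.56 and -0.76, PLK1, a mitotic kinase, by -0.45 and -0.59, and MAD2L1, a spindle checkpoint protein, by -0.78 and -0.35. The list mean was -0.22 on array 108 and -0.30 on array 109. Of 40 DNA replication and G1/S genes, 25 were lower on both and 1, the cyclin E gene CCNE1, was higher, by 0.63 and 0.51. GINS1, part of the replicative helicase, differed by -0.72 and -0.67, and CCNE2, the other cyclin E gene, by -0.61 on each array. Both lists passed limma camera with adjusted p = 6.03e-06 for each, with a prior that the ties distort. On untied genes, chosen after seeing the data, limma camera gave adjusted p = 2.71e-10 for mitosis and 0.0103 for G1/S. With an estimated correlation every list had limma camera adjusted p = 0.999, so that setting cannot tell these lists from the others. The preset correlation treats list members as nearly independent, so its p-values do not measure variation between cultures. Without the filter on low values the mitosis list did not pass (limma camera adjusted p = 0.0666).

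Replication-dependent histone genes were lower on both arrays in 13 of 19 members and higher on both in 0. Histone H1-2 differed by -0.50 and -1.45 and H4C5, below the negative control mean on array 109, by -0.56 and -0.58. The list mean was -0.14 on array 108 and -0.46 on array 109, and its adjusted p from limma camera was 0.0747. It passed in 5 of 10 alternatives, and had limma camera adjusted p = 0.999 with an estimated correlation, as did every list. Histone genes share near-identical sequences, so single members are uncertain.

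Besides ARID1A, 8 genes were at least 2-fold lower on both siRNA arrays, and 8 genes were at least 2-fold higher, of which MIR501 was counted but falls outside the naming rule. Among the higher genes were TGFB2, a TGF-beta ligand, by 1.07 and 1.32, JARID2, a polycomb cofactor, by 1.01 and 1.32, FUT3, a fucosyltransferase, by 1.09 and 1.02, and FAM222B by 1.08 and 1.19. The pseudogene OR7E91P differed by 1.55 and 1.06, while LINC00960 stayed below the negative control mean on all arrays. The next in rank were ZC3H12A, an RNase that degrades cytokine mRNAs, ATF3, LURAP1L, IRAK2, a kinase of Toll-like receptor signalling, and ZBTB47. Their log2 differences lay between 0.93 and 1.09.

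Among the lower genes were MMP3, a matrix protease, by -1.48 and -1.16, ID1, a BMP-responsive inhibitor of differentiation, by -1.24 and -1.15, and KLK13, a kallikrein protease, by -1.17 and -1.54. RPS6KA6 differed by -1.10 and -1.27, MAOB, a monoamine oxidase, by -1.25 and -1.06, LINC01151 by -1.22 and -1.51, and the histone gene H3C7 by -1.09 and -1.05. LINC01151 lay below the negative control mean on array 109. CLEC2B, a C-type lectin, had the same value on both siRNA arrays, at -1.31 from the mock array. It was the only one of the 24 genes taken by rank that both reached 2-fold and passed the designed limma fit (adjusted p = 0.00059), a call that rests on the tie. GNG11, SLC25A24, IL7R, the interleukin 7 receptor, and LINC00707, also below that mean on array 109, followed, with differences between -0.97 and -1.66.

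**Figure D1:**
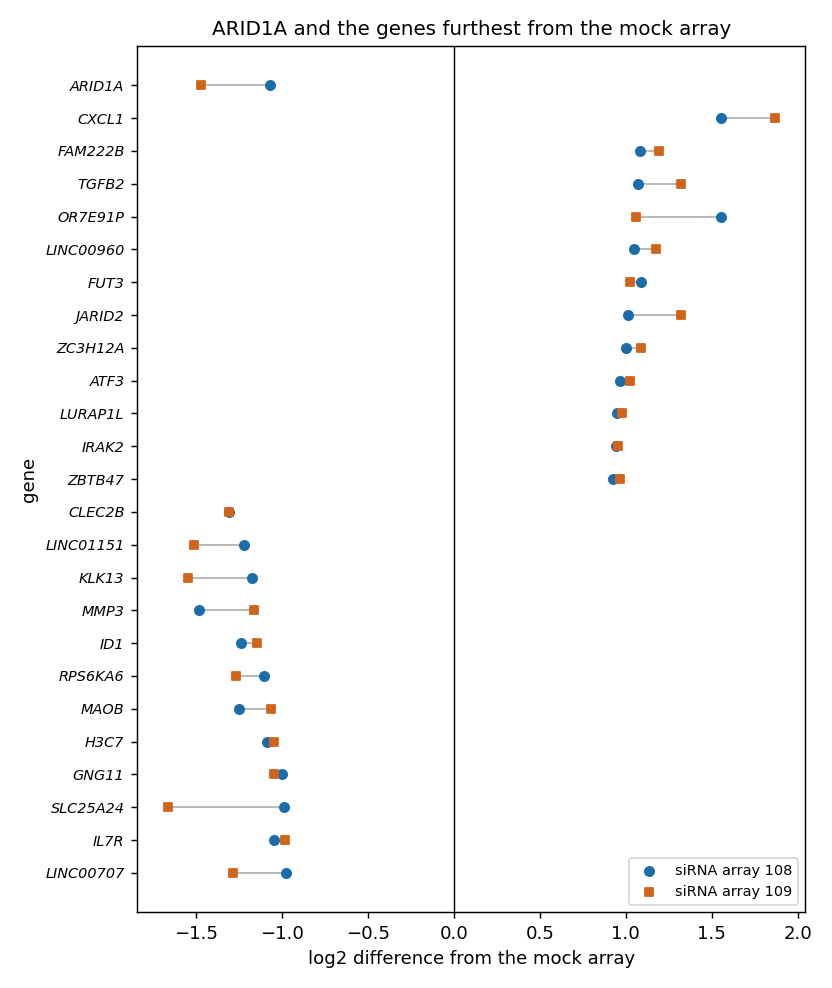
Log2 difference from the mock array (horizontal axis) for ARID1A and the 24 genes taken by rank (vertical axis), with circles for array 108 and squares for array 109. ARID1A lies at -1.07 and -1.47, and CXCL1, whose mock value is below the negative control mean and which was at least 2.79-fold higher, at measured differences of 1.55 and 1.87.

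ATF4 amino acid response genes had a mean of -0.13 on array 108 and 0.26 on array 109, and MYC target and ribosome biogenesis genes -0.17 and 0.12, each outside the central 95% of random lists on opposite sides. The average of the MYC list changed sign with the scaling. SESN2, a stress-induced regulator of mTORC1 in the ATF4 list, was nevertheless higher on both arrays, by 0.56 and 1.30. Type I interferon response genes had a mean of 0.17 on array 108, above random lists, and -0.07 on array 109, within them, with 6 of 34 members higher on both arrays and 0 lower on both. RIGI, a sensor of viral RNA, differed by 0.77 and 0.34. Epithelial junction genes had means of 0.17, above random lists, and -0.03, within them, with 11 of 26 higher on both and 3 lower. None of these lists passed limma camera as designed. The lists that follow did not pass the designed test either. EGFR ligands, with 6 members tested, had a mean of 0.05 and 0.55, where HBEGF differed by 0.48 and 1.49 and EREG by -0.14 and 1.24. The means of TGF-beta targets were -0.01 and 0.06, and of p53 target genes 0.05 and 0.07. YAP/TEAD targets had means of 0.06 and 0.17, above the central 95% of random lists on both arrays, with limma camera adjusted p = 0.649. By the median, array 108 lay within random lists, at the 71.24th percentile, and array 109 above them, at the 99.96th. Matrix protease and plasminogen genes had means of 0.05 and 0.06, within random lists, with 8 of 20 higher on both arrays and 3 lower. By the median, array 108 lay above random lists, at the 99.99th percentile, and array 109 within them, at the 53.73rd. PLAU, the urokinase gene, differed by 0.87 and 0.59, and MMP3 by -1.48 and -1.16. Genes linked to ARID1A in other cell types had a mean of 0.14 on array 108 and 0.13 on array 109. Both lay above random lists, with limma camera adjusted p = 0.655. By the median, which was 0 on each array, the list lay within random lists, at the 52.62nd percentile on array 108 and the 51.41st on array 109. Of its 19 members tested, 7 were higher on both arrays and 4 lower. The list includes IL6, at 0.62 and 1.06, and CXCL8, both shared with the NF-kB list, so the means of these lists are not independent. The mock value of CXCL8 lay below the negative control mean.

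**Figure D2:**
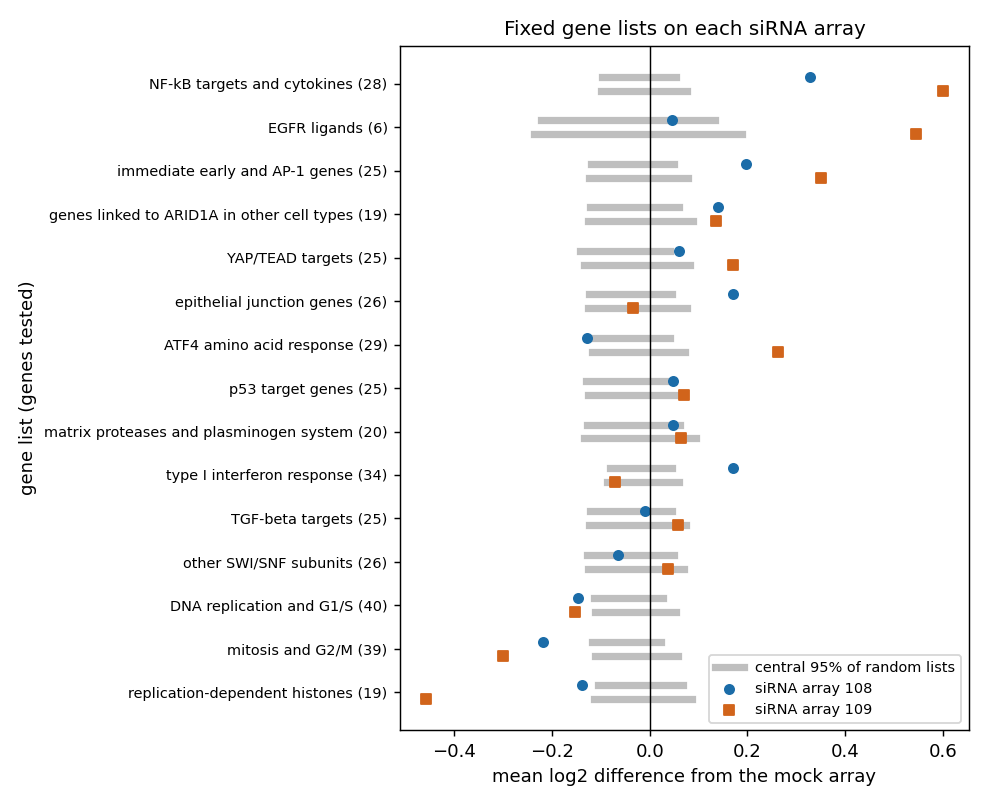
Mean log2 difference from the mock array (horizontal axis) of 15 gene lists (vertical axis, with the number of genes tested), with circles for array 108, squares for array 109 and grey bars for the central 95% of random lists matched on level. NF-kB targets lie at 0.33 and 0.60 and mitosis genes at -0.22 and -0.30, outside the bars on both arrays.

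The designed limma fit called 999 genes higher and 920 lower at a false discovery rate of 5%, but these calls cannot be used. Of these 1919 calls, 1873 had exactly tied siRNA values, the median absolute log2 difference was 0.113, and in simulated data the fit called 1874 unchanged genes. With the prior spread of the untied genes applied to all genes, limma called 0 genes, with 228 higher and 225 lower at an unadjusted p under 0.05. On untied genes alone limma also called 0, with 182 and 184 at that p.

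The siRNA arrays share the mock array, which alone makes their differences agree. Pearson's r over genes, which are not independent replicates, was 0.349, against 0.499 (0.47 to 0.528 over 100 draws) in simulated unchanged groups that share a mock array. The covariance was 0.0142, against 0.0267 simulated. The 8 higher and 9 lower genes at 2-fold compare with simulated means of 16.7 and 16.9, and with 0.0606 and 0.228 for independent lists. The simulated noise came from the distance between the siRNA arrays, which includes any real difference between them.

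The siRNA arrays were also compared with each other, 1 array against 1, with no test. Array 109 was at least 2-fold higher than array 108 in 97 genes and lower in 71. PTX3, a pentraxin of innate immunity, was 2.26 higher on array 109, the transporter SLC10A5 2.05, LINC01111 1.90, the esterase AADAC 1.90 and LINC02806 1.74. ZNF681 lay below the negative control mean on array 108 and was at least 3.81-fold higher on array 109. On array 109, LOC105370363 differed from array 108 by -2.33, the ubiquitin ligase RNF19B by -2.01 and ANXA9 by -1.96. The sugar transporter SLC2A12 lay below the negative control mean on array 109 and was at least 3.92-fold lower there. NRAS, a RAS family GTPase, was at 9.85 on array 108 and on the mock array and at 8.06 on array 109. LPCAT2, a lipid acyltransferase, was at 8.80 on array 108 and the mock array and at 7.03 on array 109. The SD over genes was 0.232 between the siRNA arrays, against 0.192 and 0.212 between each of them and the mock array.

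**Figure D3:**
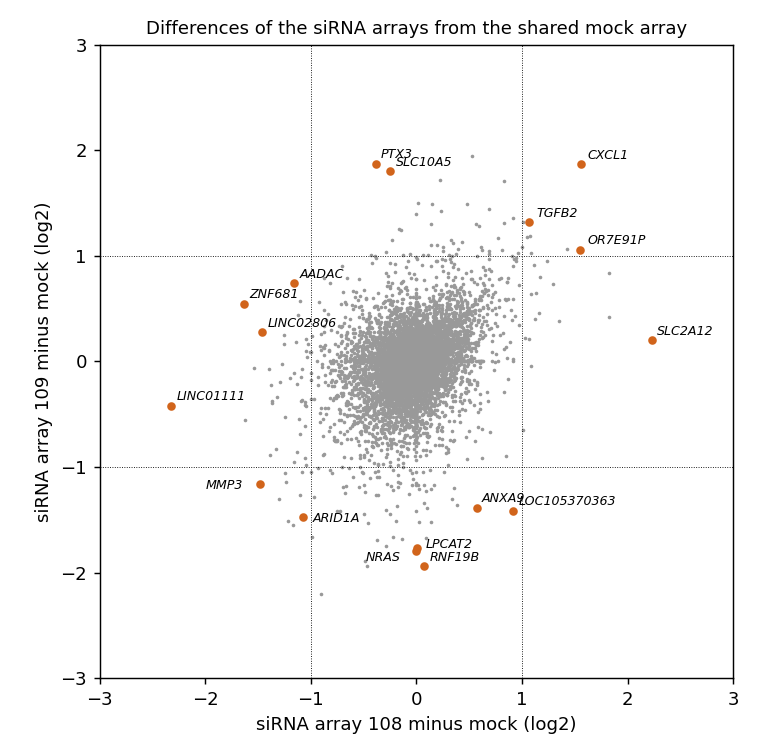
Log2 difference from the mock array of each of 20582 genes on array 108 (horizontal axis) and array 109 (vertical axis), with 2-fold limits as dotted lines and named genes in orange. CXCL1 lies high on both axes, ARID1A low on both, and NRAS at 0 on array 108 and -1.79 on array 109.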

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

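Tests of the background, of noise near it, of the interferon list, of single RNA, of joint summary, of array-wide signal, of silencing by siRNA sequence, of the splits and of knockdown were chosen after the values they use were seen.

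Main probe sets without a gene symbol, 13495 in all, were outside the comparisons. Among them 2 were at least 2-fold higher and 4 at least 2-fold lower than in the mock array on both siRNA arrays, above the negative control mean on the brighter side.

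NF-kB genes were higher than in the mock array on both siRNA arrays in 16 of 28 (limma camera adjusted p = 0.336). Mitosis and G1/S genes were lower in 35 of 39 and 25 of 40. Their limma camera adjusted p was 6.03e-06 each with the prior that the ties distort, and 2.71e-10 and 0.0103 on untied genes. These p-values treat list members as nearly independent. With an estimated correlation every list had limma camera adjusted p = 0.999. A shared difference in background or RNA quality stays open. The mean log2 shift of 3575 intron control sets was -0.098 on array 108 and 0.118 on array 109, so the normalized values held no shared shift. The authors' normalization sets array-wide levels, however, and no measure of RNA quality was used here. Noise near the background is argued against for the NF-kB part. Its 19 members whose mock value lay above the negative control mean shifted by 0.368 and 0.719. Both shifts lay above the central 95% of random lists drawn by mock value. Interferon sensing of transfected RNA stays open, because the interferon list was at -0.0715 on array 109, at the 5.7th percentile of random lists, but above the central 95% of them on array 108. Knockdown, transfection and an unusual mock array cannot be told apart with 1 mock array: 126 genes were at least 1.5-fold from both others on the mock array, against 206 on array 108 and 292 on array 109.

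Many genes had identical values on several arrays. A floor at low values as the whole cause is argued against, since 29.6% of the 13529 genes identical on all arrays had a mean level above the negative control mean. The siRNA arrays were not tied clearly more often than other pairs. On these alone 2099 genes were tied, against 2004 on array 108 and the mock alone and 2097 on array 109 and the mock alone. A single RNA on both siRNA arrays stays open, because ties made in the processing could fall on all pairs alike. A joint summary of probes over the arrays, such as median polish, may set small differences to 0 and stays open, because probe values were not used here. Exon control sets were identical on all arrays in 0.7%, against 43.9% of all probe sets. No biological explanation was tested.

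Genes at least 2-fold apart on array 108 alone were low there in 85.2% of 27, and on array 109 alone in 71.7% of 60, against 47.1% of 17 on the mock array alone. At 1.5-fold the contrast was smaller, with 78.2% of 206, 63.4% of 292 and 55.6% of 126. Against the mock array, Fisher's exact test, which treats genes as independent, gave two-sided p = 0.0155 and 2.5e-05 for array 108 at these sizes, but 0.0817 and 0.155 for array 109. Silencing of other genes by each siRNA sequence therefore stays open, as do genes that vary between cultures, and the siRNA sequences needed to search for matching sites were not used here. A lower signal of the whole array stays open, because the authors' normalization sets array-wide levels, after which polyA spike sets differed from the mock array by a mean log2 of 0.045 on array 108 and -0.169 on array 109.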

How the results depend on the processing

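The cause of these moves was not tested unless stated. ARID1A was -1.27 and between -1.07 and -1.47 without 1 siRNA array, and passed the threshold in no setting run. Designed limma counts of 999 higher and 920 lower became 0 and 0 under quantile scaling, median centring and cyclic loess, which break the ties, and 0 and 0 with the added fits. They were 498 and 525 with the 50th percentile filter, 99 and 91 against 1.2-fold, and 1496 and 1467 with no filter. Genes at 1.5-fold on both arrays were 70 higher and 56 lower, by the looser rule, and 762 differed between the siRNA arrays. Simulated unchanged groups sharing a mock array gave more, 124 (101 to 154) and 124 (90 to 145). Their noise includes any real difference between the siRNA arrays. Single arrays gave 24 to 52 genes higher and 54 to 87 lower at 2-fold. Lists passing limma camera, 0 higher and 2 lower, were 7 and 3 under quantile scaling, 7 and 5 under median centring, 3 and 3 under cyclic loess, 2 and 2 with the 50th percentile filter, 0 and 1 with no filter, 4 and 7 on ranks, 1 and 4 at 10%, 6 and 4 on untied genes, and 0 and 0 with an estimated correlation. Of 1051 tested values of named genes and lists under other settings, 971 kept their side of the threshold, 46 gained it and 34 lost it, not counting the per-sample tables, which hold the same values. Without 1 siRNA array, 16 of 40 list shifts had opposite signs on the arrays; with 2 replicates such a value always lies within 1 SD, so it says nothing about stability. Signal over background limits genes below the negative control mean.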

Other observations

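The ontology tests and the splits were added after seeing the data. Among genes at least 1.5-fold higher on both siRNA arrays, 20 had gene ontology terms, and 5 of these, CXCL1, IRAK2, NFKBIZ, SERPINA3 and TNIP1, belonged to the inflammatory response, against 0.227 by chance (hypergeometric test over 1314 terms, Benjamini-Hochberg adjusted p = 0.00313). Among 39 such lower genes, 7 belonged to chromatin organization, against 0.675 by chance (adjusted p = 0.00529). These were ARID1A itself and the histone genes H2AC13, H2AC15, H2AC21, H2BC10, H3C12 and H3C7, which share near-identical sequences. Nucleosome assembly, with 5 genes, had adjusted p = 0.0185, and 0.0738 over all 6 selections, where the other terms had 0.0159. These p-values treat genes as independent. Both selections share the mock array, and hold 70 higher and 56 lower genes. Simulated unchanged groups that share one held more, 124 (101 to 154) and 124 (90 to 145). The noise in that simulation includes any real difference between the siRNA arrays.

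Heat shock and cytosolic chaperone genes were lower on both arrays in 10 of 14 members and higher on both in 0, with a mean of -0.10 on array 108, within the central 95% of random lists, and -0.19 on array 109, below it (limma camera adjusted p = 0.273). DNA repair genes were lower on both in 14 of 36 and higher on both in 0. Their means of -0.11 and -0.07 lay within the central 95% of random lists (limma camera adjusted p = 0.0988). By the median, array 108 lay below that range, at the 0.68th percentile, and array 109 within it, at the 8.3rd.

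Taking each array in turn as the lone one gives 3 splits, too few for a share under 0.05. The mock array as the lone one gave 3 ontology terms, and the highest of the other splits 0, so 1 of the splits gave as many. Fewer terms, inflammatory response and chromatin organization, passed when adjusted over all 6 selections. By other measures the mock array did not stand out. By the mean, the NF-kB, immediate early, mitosis and histone lists lay beyond random lists on both differences for the mock. They also did so for array 109 as the lone one. By the median, the mitosis list lay within random lists between the siRNA arrays, with a median difference of 0, at the 43.7th percentile. The counts of lists that follow use the mean. Lists beyond random lists on both differences numbered 7 for the mock, 9 for array 108 and 8 for array 109, and limma with the prior of the untied genes called 0, 0 and 40 genes.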
